A study of Mus musculus with 14 samples.

How the data were processed

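Expression was measured on 14 Affymetrix exon arrays of mouse cortex and hippocampus at postnatal day 7, from mice with floxed Ctcf alleles with or without Cre in the Neurod6 (Nex) locus. The deposited values are log2 expression values per probe set. Per the submitters' processing notes, the authors used Affymetrix Expression Console, RMA and Partek 6.4 with the mm9 build. The set of arrays normalized together and the versions of Expression Console and RMA are not given in the sources used here. The values were used as deposited, with no filter, for 23332 probe sets.

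Groups were taken per the labels, with 4 control and 4 cKO arrays of cortex and 3 control and 3 cKO arrays of hippocampus. Gene names came from the annotation of the probe sets, in which 14996 carried 1 symbol (14860 genes), 1019 several and 7317 none. A reference table of another assembly than mm9 gave gene names and the order of neighbouring genes only. The median of 719 olfactory receptor probe sets, 3.55, served as a guide to background, with 2151 probe sets at or below it on average.

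A linear model with 1 mean per group was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, with eBayes and Benjamini-Hochberg adjustment over all probe sets within a comparison. A probe set was called at an adjusted p under 0.05 and a fold change above 1.2, the thresholds the series text names for its ANOVA. Total counts of genes changed or different in a comparison are counts of called probe sets, some of them with no symbol or several. The comparisons were cKO minus control in cortex and in hippocampus, their average, their difference, and hippocampus minus cortex in controls. SE is the moderated standard error, SD the spread of a group's arrays. For Ctcf a two-sided exact permutation test was run within each region. Overlaps were tested one-sided with Fisher's exact test over all probe sets.

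Of 42 gene lists fixed before the data were examined, 40 had at least 5 measured members and were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists within a comparison, with camera at an estimated correlation and fry beside it. Members were also adjusted over the list alone. The protocadherin alpha and gamma clusters had no member with a symbol of its own and are not analysed here.

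Genes were named by a rule. Ctcf and Neurod6 were always named. In cortex and in hippocampus the 10 largest rises and 10 largest falls were named among calls with 1 symbol in which every cKO array lay on the same side of every control array. For the other comparisons the 5 largest each way were named, and of each list up to 4 members with the smallest p. Any clustered protocadherin was open to naming. Genes named outside this rule are said to have been chosen after their values were seen.

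Arrays were compared in pairs by Spearman correlation over all probe sets and by the SD of their difference. Alternatives chosen after the arrays had been compared left out the 3 arrays labelled hippocampus that match a cortex array, added Y-linked signal (the mean of Eif2s3y and Kdm5d, in 2 classes) as a covariate, used the cortex arrays alone with and without the 2 that lack Y-linked signal, and subtracted the mean difference of the 3 matching pairs. The fits with the covariate and with the subtraction also left out the 3 matching arrays, and the error of the subtracted difference does not enter SE or p. Alternatives chosen earlier were quantile normalization again, centring on array medians, a filter on low values, contrasts without moderation, eBayes with trend and robust, array weights, replicate number as a fixed or random block, 1 probe set per gene, no fold minimum or a fold of 1.5, the compared groups alone, and leaving out each array in turn. The cortex calls were followed into the unmatched hippocampus arrays against 10000 random lists of the same size.

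The procedure was tested on simulated data with 50 changed genes per fold. In cortex it recovered 28% at 1.3-fold, 54% at 1.5-fold, 78% at 2-fold and 84% at 3-fold, with 4 false calls. For hippocampus it recovered 12%, 44%, 76% and 86%, with 10 false calls. Of 40 lists the 1 that was shifted was called, and no other. The simulated arrays were independent, with noise drawn separately for each probe set and its SD taken from the cortex arrays. They held no matching arrays and no correlation between genes. The rates for hippocampus therefore do not describe the arrays so labelled. Nor can the list check show how specific camera is when genes vary together.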

Results

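Gene expression was measured on 14 Affymetrix exon arrays of mouse brain tissue from postnatal day 7, all labelled as male. In the conditional knockout (cKO), Cre recombinase expressed from the Neurod6 locus (also called Nex), which is active in excitatory neurons of the cortex and hippocampus, recombined floxed alleles of Ctcf. CTCF is a zinc finger protein that binds insulator sites and, with cohesin, anchors chromatin loops. Controls carried the same floxed alleles without Cre. The labels gave 4 control and 4 cKO arrays of cortex, and 3 control and 3 cKO arrays of hippocampus. Array medians lay between 6.57 and 6.77 on the log2 scale, and single values between 0.413 and 14.0. The number of arrays limited the precision of every value. The labels call the arrays of a group biological replicates but name no animal for an array, and the p-values measure only the spread between these arrays.

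The genes that set hippocampus apart from cortex divided the arrays labelled hippocampus. Prox1, a transcription factor of dentate granule cells, lay between 8.91 and 9.28 on 3 of these 6 arrays and between 6.65 and 6.91 on the other 3, against 6.61 to 7.20 on the 8 cortex arrays. Zbtb20, a transcription factor of hippocampal pyramidal neurons, lay between 10.4 and 10.6 on the first 3 and between 8.37 and 8.67 on the other 3, against 8.07 to 8.61 in cortex. The glutamate receptor gene Grik4 lay between 9.23 and 9.48 on the first 3, and between 7.38 and 8.09 on the other 3. The layer 4 gene Rorb and the upper layer gene Cux2 ran the other way. Rorb lay between 7.14 and 7.58 on the first 3 arrays and between 9.33 and 9.45 on the other 3, where cortex ranged from 9.49 to 9.89. Cux2 lay between 7.49 and 7.87 on the first 3 and between 8.92 and 9.22 on the other 3, where cortex ranged from 9.07 to 9.52. These example genes were chosen after their values were seen, from lists fixed beforehand.

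Each of the 3 arrays with cortical levels matched 1 cortex array of the same genotype over all probe sets. The array labelled hippocampus control 2 matched cortex control 3, hippocampus cKO 1 matched cortex cKO 3, and hippocampus cKO 3 matched cortex cKO 2. The lowest Spearman correlation within these 3 pairs was 0.997, and the highest among all other pairs of arrays was 0.990. The difference within a matching pair had an SD of at most 0.213 on the log2 scale, against at least 0.363 for any other pair. Counts, lists and most genes on the arrays labelled hippocampus are therefore given as labelled and without the 3 matching arrays. Without them 2 control arrays and 1 cKO array are left, and the single cKO array is assumed to vary like the other groups.

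**Figure D1:**
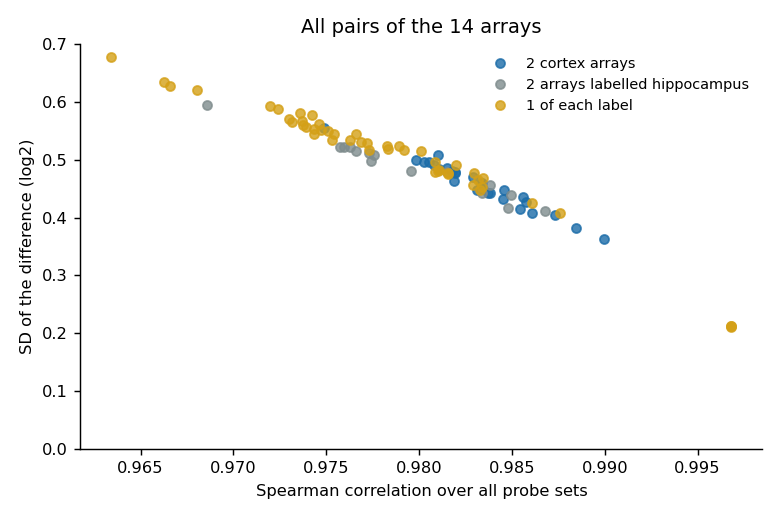
Each point is 1 pair of the 14 arrays, with the Spearman correlation over all 23332 probe sets on the x axis and the SD of the log2 difference on the y axis. The 3 matching pairs lie together at a correlation of 0.997 and an SD of at most 0.213, apart from all other pairs.

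**Figure D2:**
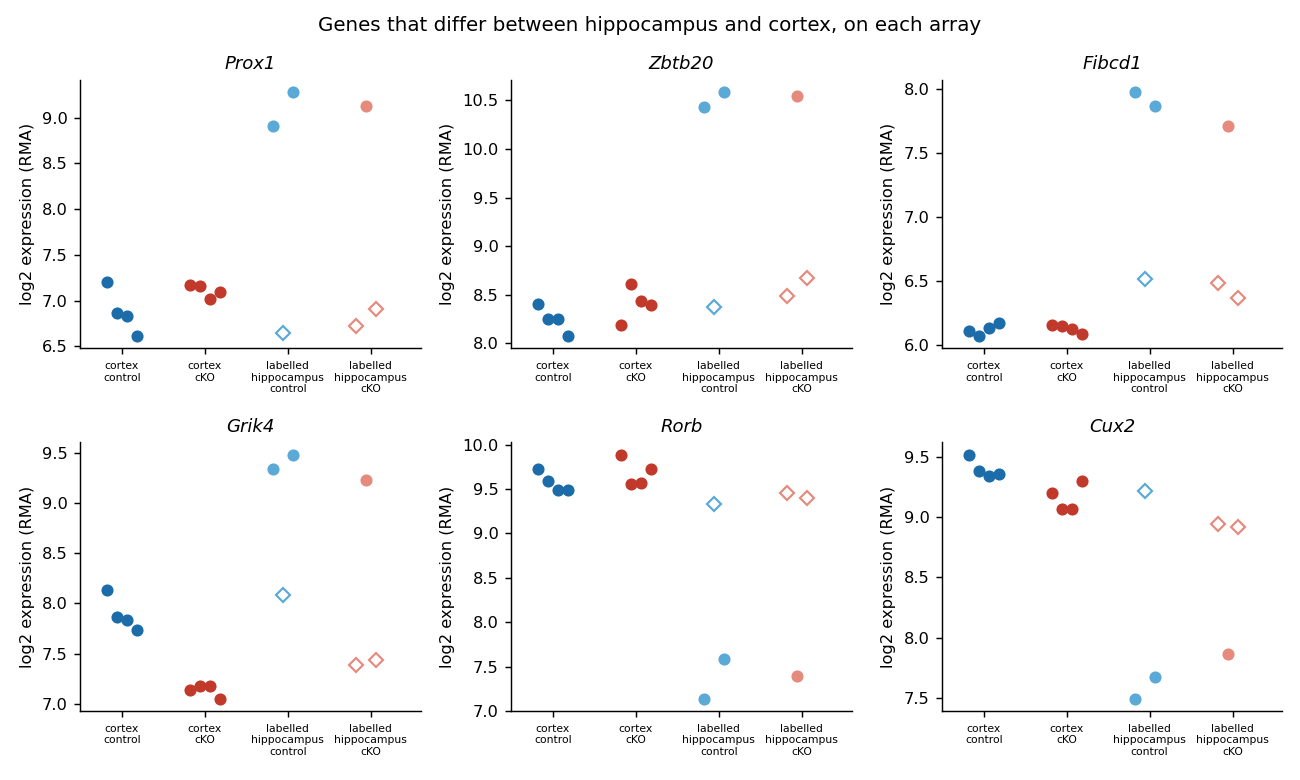
Log2 expression (y axis) of 4 genes higher in hippocampus and 2 genes higher in cortex, on each array of the 4 labelled groups (x axis). Open diamonds are the 3 arrays labelled hippocampus that match a cortex array, and they lie near the cortex arrays in every panel (Prox1 between 6.65 and 6.91, against 8.91 to 9.28 on the other 3).

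The Y-linked genes Eif2s3y and Kdm5d, whose transcripts are found only in males, divided the arrays as well. Their mean was at least 7.91 on 10 arrays and at most 4.10 on cortex cKO 1, cortex cKO 4, hippocampus control 1 and hippocampus cKO 2, although all 14 were labelled male. Eif2s3y read 3.03 and 3.04 on the cortex cKO arrays 1 and 4, and between 8.61 and 9.01 on the other 6 cortex arrays. Counts with Y-linked signal as a covariate come from fits that also leave out the 3 matching arrays.

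The targeted gene was lower on every cKO array. Ctcf (probe set 6978845) read 9.29, 9.23, 9.22 and 9.18 on the cortex control arrays 1 to 4, and 7.79, 7.94, 7.74 and 7.78 on the cortex cKO arrays. It fell 2.67-fold in cortex, from 9.23 ± 0.05 to 7.81 ± 0.09 (SD, n = 4 per group, log2 change -1.42, SE 0.12, adjusted p = 8.54e-05), to 37.4% of the control level. A two-sided exact permutation test of the 8 cortex arrays gave p = 0.0286, the smallest it can give. On the arrays labelled hippocampus Ctcf read 8.95, 9.22 and 9.16 in control 1 to 3, and 7.70, 8.31 and 7.89 in cKO 1 to 3. The change there was -1.14 (SE 0.13, n = 3 per group, adjusted p = 0.00476), 45.3% of the control level, and the two-sided exact p was 0.1, the smallest that 3 arrays against 3 allow. Without the 3 matching arrays it was -0.75 (SE 0.13, adjusted p = 0.172). Which part of the gene the probes cover is not given in the sources used here, and the tissue also holds cells in which Neurod6, and so Cre, is not expressed.

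Neurod6, the gene whose locus carries Cre, fell 3.66-fold in cortex, from 10.25 ± 0.13 to 8.37 ± 0.46 (SD, n = 4 per group, log2 change -1.87, SE 0.29, adjusted p = 0.00595). Its 95% interval ran from -2.50 to -1.25. On the arrays labelled hippocampus the change was -1.95 (SE 0.33, adjusted p = 0.0336), and -1.19 (SE 0.36, adjusted p = 0.516) without the matching arrays, and the call also ended without hippocampus cKO 3 alone (adjusted p = 0.192).

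**Figure D3:**
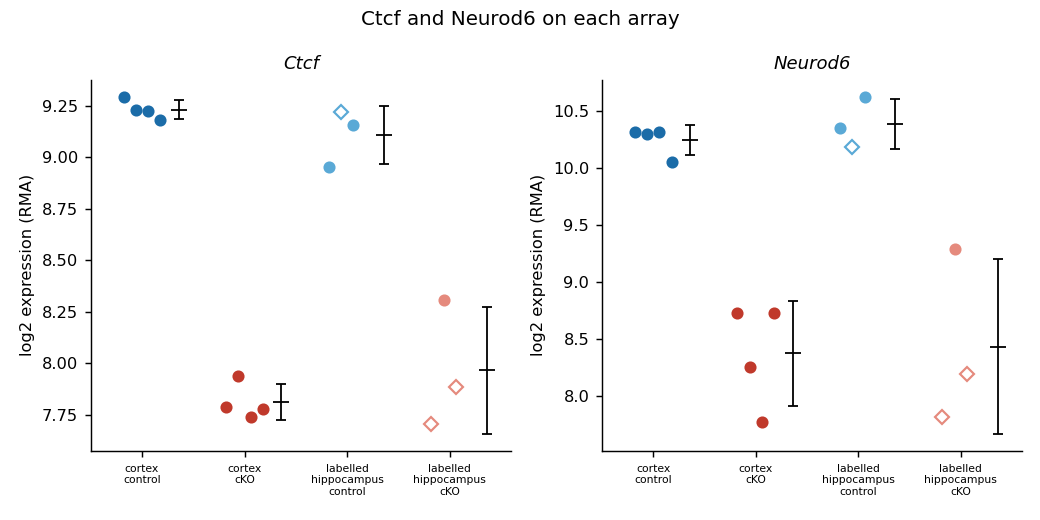
Log2 expression (y axis) of Ctcf and Neurod6 on each array of the 4 labelled groups (x axis), with the mean and SD of each group as a bar beside its points. Open diamonds are the 3 matching arrays. Cortex Ctcf lies at 9.23 ± 0.05 in control and 7.81 ± 0.09 in cKO.

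The cortex comparison shows which transcripts differed between cKO and control cortex. No group carried Cre without floxed Ctcf alleles. Effects of Ctcf deletion, of Cre and of the lower Neurod6 level therefore cannot be told apart. Y-linked signal was also unbalanced between the 2 groups. The largest rise was that of Mnd1, a meiotic recombination gene, which went from 4.46 to 7.00 (5.81-fold, log2 change 2.54, SE 0.24, n = 4 per group, adjusted p = 0.000282). Bbx, a gene with an HMG box, rose by 1.23 (SE 0.12), and Lurap1l by 1.39 (SE 0.12, adjusted p = 9.59e-05). Fcgr3, an Fc receptor of microglia and other myeloid cells, rose by 1.42 (SE 0.21), protein kinase D1 (Prkd1) by 1.21 (SE 0.19), the melanocortin receptor Mc5r by 1.21 (SE 0.20), and Rin1, a Ras effector of neurons, by 1.18 (SE 0.17). The largest fall was that of Ajm1, an apical junction gene, from 9.18 to 7.20 (3.95-fold, log2 change -1.98, SE 0.15, adjusted p = 6.89e-05).

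Rasgrp1, an exchange factor that activates Ras, fell by 1.91 on the log2 scale (SE 0.32), and Il1rapl2, a synaptic relative of interleukin receptors, fell by 1.87 (SE 0.33). Rprm, a gene of deep layer cortical neurons, fell by 1.74 (SE 0.23, 3.35-fold). The 10 largest falls also held Neurod6, 4 protocadherin beta isoforms and Hbq1a, an alpha-like globin (-1.63, SE 0.30). The 10 largest rises also held Defb5, a beta-defensin (1.90, SE 0.30), Extl1, of a family of heparan sulfate glycosyltransferases (1.83, SE 0.35), and Pqlc3 (1.33, SE 0.28). The control level of Defb5, 2.80, lay below 3.55, the median of 719 olfactory receptor probe sets, which serve here as a guide to background. In each of these 20 genes every cortex cKO array lay on the same side of every cortex control array, as the rule that chose them required. Extl1, Pqlc3 and Hbq1a were no longer called without single arrays, with adjusted p up to 0.0741 for Extl1 (without cortex cKO 3), 0.127 for Pqlc3 (without cortex cKO 2) and 0.0675 for Hbq1a (without cortex cKO 1).

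Of 23332 probe sets, 355 passed limma's test at an adjusted p under 0.05 and a change above 1.2-fold, 107 higher and 248 lower in cKO cortex. Of these, 322 carried 1 gene symbol. With the cortex arrays alone 396 passed, and without the 3 matching arrays 455, which became 282 when Y-linked signal was added as a covariate, 201 of them among the 355. The cortex arrays without the 2 that lack Y-linked signal gave 56 (14 higher, 42 lower), 45 of them among the 355. All 355 kept the sign of their change in these last 2 fits, with a median ratio to the change as labelled of 0.999 with the covariate and 0.997 without the 2 arrays, though the 355 were chosen with those arrays included. The number of genes changed in cortex fell to 225 without cortex control 3, 229 without control 4, 216 without cKO 1, 219 without cKO 2, 212 without cKO 3 and 207 without cKO 4.

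The protocadherin beta isoforms, neuronal adhesion molecules encoded by 22 neighbouring genes, fell almost throughout. Of the 22 measured, 20 fell in cKO cortex over all probe sets, 21 adjusted over the list alone, and none rose. The median change was -1.32, a 2.49-fold fall. Pcdhb19 fell most, from 8.02 to 6.19 (3.57-fold, log2 change -1.83, SE 0.16, n = 4 per group, adjusted p = 0.000144), followed by Pcdhb22 (-1.67, SE 0.16), Pcdhb12 (-1.65, SE 0.18) and Pcdhb13 (-1.63, SE 0.21). Among the smaller falls were Pcdhb2 (-0.88, SE 0.12) and Pcdhb11 (-0.92, SE 0.13). The exceptions were Pcdhb6, with a change of -0.40 (SE 0.09, adjusted p = 0.0528), and Pcdhb1, whose level of 3.02 lay below background, with a change of 0.16 (SE 0.30) that turned to -0.12 without cortex control 1. Pcdhb6 passed without cortex control 2 (adjusted p = 0.0367) and without hippocampus control 2 (adjusted p = 0.0493).

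As a list, the isoforms were lower than other genes (camera adjusted p = 1.27e-43, and adjusted p = 0.0160 with an estimated correlation). With the cortex arrays alone the latter was 0.0971. The cortex arrays without the 2 that lack Y-linked signal gave 6 falls over all probe sets and 21 adjusted over the list alone, with a median of -1.29. On the arrays labelled hippocampus 10 isoforms fell over all probe sets, and 21 adjusted over the list alone, with a median of -0.95. Without the 3 matching arrays limma called 0, and 7 adjusted over the list alone, with 21 of 22 changes negative and a median of -0.60. Among them were Pcdhb22 at -1.13 (SE 0.29, adjusted p = 0.375) and Pcdhb20 at -0.77 (SE 0.16, adjusted p = 0.247). The count of 10 fell to 4 without cortex control 3 or 4, 5 without cortex cKO 1, 6 without cortex cKO 2, 5 without hippocampus control 1 or 2, 3 without hippocampus control 3, 1 without hippocampus cKO 1 and 2 without hippocampus cKO 3, and was 18 without hippocampus cKO 2. The alpha and gamma clusters are not analysed here, because no probe set carried 1 of their symbols alone.

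**Figure D4:**
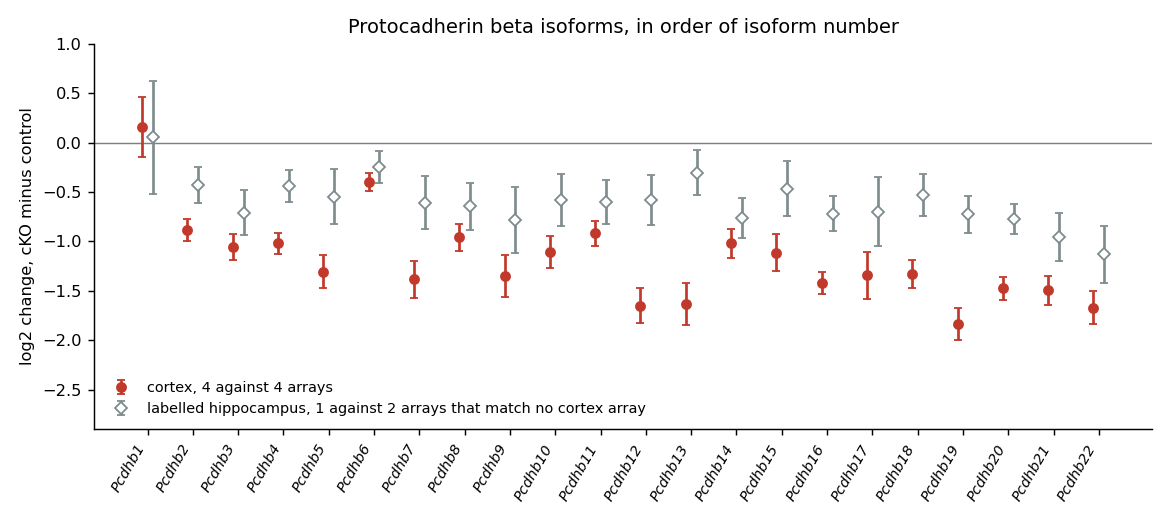
Log2 change, cKO minus control (y axis), of the 22 protocadherin beta isoforms (x axis) in cortex (filled circles, 4 arrays against 4) and on the 3 arrays labelled hippocampus that match no cortex array (open diamonds, 1 against 2). Bars are standard errors. In cortex 21 of 22 changes lie below 0, with a median of -1.32, and on the hippocampus arrays 21 of 22, with a median of -0.60.

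Genes of the deep cortical layers fell as a group. Of 19 measured, 6 fell over all probe sets and 9 adjusted over the list alone, and 15 changes were negative, with a median of -0.48 (camera adjusted p = 4.07e-08, and adjusted p = 0.0391 with an estimated correlation, which became 0.160 with the cortex arrays alone). Fezf2, the transcription factor that specifies subcerebral projection neurons, fell 3.09-fold, from 9.89 to 8.27 (log2 change -1.63, SE 0.13, n = 4 per group, adjusted p = 8.51e-05). The zinc finger gene Tshz2 fell by 1.12 (SE 0.18, adjusted p = 0.00698), the neurexophilin Nxph3 fell by 0.86 (SE 0.11, adjusted p = 0.00152), and Pcp4, a calmodulin-binding peptide, fell by 1.25 (SE 0.24, adjusted p = 0.0200). The call of Pcp4 ended without each of 5 arrays, with an adjusted p of up to 0.0725 (without cortex cKO 3). Of 19 upper layer genes none was called over all probe sets by limma as labelled, and 1 higher and 2 lower were called adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.956). Among them Unc5d stood at 0.49 (SE 0.12, adjusted p = 0.0760), Plxnd1 at -0.60 (SE 0.15, adjusted p = 0.0868) and Lmo4 at -0.44 (SE 0.11, adjusted p = 0.0944). With the cortex arrays alone, and again without the matching arrays, 1 higher and 2 lower were called over all probe sets. The adjusted p was then 0.0280 and 0.0141 for Unc5d and 0.00559 and 0.00231 for Plxnd1.

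Glial, vascular and metabolic lists moved by small amounts, and none of their calls held with an estimated correlation. Microglial genes were higher, 23 of 26 with a positive change and a median of 0.23 (adjusted p = 2.60e-05, and adjusted p = 0.897 with an estimated correlation), but Fcgr3 alone was called, over all probe sets and over the list alone. Trem2 stood at 0.39 (SE 0.13), C1qc at 0.41 (SE 0.19) and Csf1r at 0.43 (SE 0.21). All 18 cholesterol synthesis genes had a negative change, with a median of -0.22 (adjusted p = 0.000192, and adjusted p = 0.780 with an estimated correlation), and limma called none, over all probe sets or over the list alone. Among them were Mvd at -0.31 (SE 0.11) and Insig1 at -0.27 (SE 0.07). Of 31 potassium channel genes 3 fell, and 7 adjusted over the list alone, with a median of -0.19 (adjusted p = 0.000218, and adjusted p = 0.582 with an estimated correlation). Kcnh1 fell by 1.33 (SE 0.21), Kcnj6 by 0.50 (SE 0.09) and Kcnk2 by 0.48 (SE 0.09), the latter 2 with an adjusted p of up to 0.0719 (Kcnj6 without cortex cKO 4) and 0.0864 (Kcnk2 without cortex cKO 1).

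Of 32 activity-regulated genes 28 had a negative change, with a median of -0.19 (adjusted p = 0.00210, and adjusted p = 0.582 with an estimated correlation). Dusp6, a phosphatase induced by ERK signalling, was the 1 member called, over all probe sets and over the list alone (-0.55, SE 0.10), with an adjusted p of up to 0.0690 without cortex cKO 1. Junb stood at -0.27 (SE 0.09) and Dusp1 at -0.26 (SE 0.09). Meninges and fibroblast genes had a median of 0.11 (adjusted p = 0.00501, and adjusted p = 0.626 with an estimated correlation) and astrocyte genes one of 0.07 (adjusted p = 0.0323, and adjusted p = 0.997 with an estimated correlation). Endothelial and pericyte genes had a median of -0.17 (adjusted p = 0.0108, and adjusted p = 0.997 with an estimated correlation). None of these 3 lists held a gene called over all probe sets, and adjusted over the list alone 2 endothelial genes fell. The astrocyte list lost its call without cortex control 2 or 3 and without cortex cKO 2 or 3 (adjusted p of up to 0.258), and the endothelial list without cortex control 4 (0.0728).

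The other 31 lists were not called in cortex as labelled, with adjusted p from 0.0752 to 0.990. Single members of some of them were called. Grm8, a metabotropic glutamate receptor, fell by 1.46 (SE 0.19), the axon guidance receptor Ephb1 fell by 0.82 (SE 0.12) and the type II cadherin Cdh22 fell by 0.65 (SE 0.11). The axon guidance receptor Robo1 rose by 0.60 (SE 0.10) and the heat shock gene Dnajb4 by 0.56 (SE 0.10). The imprinted gene Plagl1 rose by 0.93 (SE 0.16) and the cohesin subunit gene Stag1 by 0.50 (SE 0.11). Falls were called for Slc6a4 (-0.62), Cd44 (-0.66), Sulf1 (-0.65), Mthfd2 (-0.63), Man1a (-0.50), Lrrtm2 (-0.42) and the p53 targets Plk3 (-0.44) and Aen (-0.35). Each of the 8 genes in the last list, with Plagl1 and Stag1, lost its call without single arrays, with adjusted p of up to 0.0507 for Plagl1 without cortex cKO 3 and 0.151 for Plk3 without cortex cKO 2. Interneuron genes had a median of -0.03 (camera adjusted p = 0.962), with Sst at -0.43 (SE 0.15) and Reln at -0.24 (SE 0.12).

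Among these lists, in the fit of the arrays as labelled, heat shock genes had a median of 0.13 (camera adjusted p = 0.0752, and called at 0.0412 with the cortex arrays alone and 0.0351 without the matching arrays), oligodendrocyte lineage genes 0.10 (0.0845), glycolysis and hypoxia genes -0.13 (0.108), oxidative phosphorylation genes 0.04 (0.138) and neuropeptide genes -0.18 (0.139). Nonclustered protocadherins had a median of 0.14 (0.373), choroid plexus genes 0.03 (0.416), interferon response genes 0.04 (0.416), striatal genes -0.13 (0.490), cohesin genes 0.00 (0.513) and immature neuron genes -0.15 (0.633). Imprinted genes had a median of -0.03 (0.723), cadherins 0.06 (0.815), excitatory neuron identity genes -0.05 (0.828), hippocampal subfield genes -0.09 (0.828), blood genes -0.05 (0.828), progenitor genes -0.04 (0.828), axon guidance genes -0.08 (0.828) and ribosomal protein genes 0.01 (0.828). Thalamic genes had a median of -0.01 (0.844), GABA receptor genes -0.06 (0.849), synapse scaffold and adhesion genes -0.02 (0.849), glutamate receptor genes -0.01 (0.880), reactive astrocyte genes 0.04 (0.957), p53 targets 0.00 (0.962) and unfolded protein response genes -0.04 (0.962). Inflammatory cytokine genes had a median of 0.02 (0.962), neuronal maturation genes -0.01 (0.990) and Hox genes -0.02 (0.990). Median, mean and test differed in sign for the cohesin, imprinted, reactive astrocyte, progenitor, neuronal maturation, synapse, p53, cytokine and Hox lists, none of which was called as labelled. The lists called in cortex numbered 9 as labelled, 10 with the cortex arrays alone and 10 without the matching arrays, with heat shock as the one added. With Y-linked signal as a covariate and without the matching arrays 13 were called. Heat shock (adjusted p = 0.0206), oligodendrocyte lineage (0.0206), choroid plexus (0.0110), cadherins (0.0451) and neuronal maturation (0.0451) were added there, and endothelial cells and pericytes were no longer called. With an estimated correlation camera called none in these 3 alternative fits.

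On the arrays labelled hippocampus, the largest rise was again that of Mnd1 (4.71-fold, log2 change 2.24, SE 0.28, n = 3 per group, adjusted p = 0.00678), which stood at 2.43 (SE 0.45, adjusted p = 0.212) without the 3 matching arrays. Oxtr, the oxytocin receptor gene, rose by 1.56 (SE 0.23, and 1.68 without the matching arrays), Mettl25 by 1.25 (SE 0.10, and 1.20), Gpld1 by 1.23 (SE 0.21, and 0.92), Coch by 1.18 (SE 0.15, and 1.06), Lurap1l by 1.14 (SE 0.13, and 0.84), Bbx by 1.12 (SE 0.14, and 0.70), Rin1 by 1.06 (SE 0.19, and 0.68) and Fdxacb1 by 1.04 (SE 0.18, and 0.97). The largest fall was that of Nts, the neurotensin gene (5.18-fold, log2 change -2.37, SE 0.44, adjusted p = 0.0470), which stood at -2.46 (SE 0.39, adjusted p = 0.127) without the matching arrays. Rasgrp1 fell by 2.01 (SE 0.37, and -2.09 without them), Ajm1 2.83-fold (SE 0.17 on the log2 scale, and -1.26), Fezf2 by 1.43 (SE 0.15, and -0.97) and Mdp1 by 1.17 (SE 0.20, and -0.86). The 10 largest falls also held Neurod6, Ctcf, Pcdhb22 (-1.42, SE 0.19), Pcdhb19 (-1.25, SE 0.19) and Pcdhb20 (-1.08, SE 0.13).

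As labelled, 78 probe sets passed, 33 higher and 45 lower, and 2009 had an unadjusted p under 0.05. Without the 3 matching arrays 1 passed, an unnamed probe set (4332799, log2 change -2.32, SE 0.21, adjusted p = 0.0371), and 1448 had an unadjusted p under 0.05. Without the matching arrays and with Y-linked signal as a covariate limma called 0 (1447 at an unadjusted p under 0.05), and with the 6 arrays labelled hippocampus alone 0 (1444). The count of 78 genes changed in hippocampus fell to 51 without cortex control 3, 48 without cortex control 4, 50 without cortex cKO 2, 51 without cortex cKO 4, 33 without hippocampus control 1, 29 without hippocampus control 3, 14 without hippocampus cKO 1 and 19 without hippocampus cKO 3. It was 119 without hippocampus control 2 and 274 without hippocampus cKO 2. The calls of Nts and Rasgrp1 ended without single arrays, with adjusted p of up to 0.221 for Nts and 0.236 for Rasgrp1 without hippocampus cKO 1, that of Oxtr without hippocampus cKO 3 (adjusted p = 0.0835), that of Mdp1 without hippocampus cKO 3 (adjusted p = 0.190), and those of Bbx and Coch without hippocampus cKO 1 (adjusted p = 0.0514 for each). Also ended were those of Rin1 without hippocampus cKO 1 (adjusted p = 0.228) and, without hippocampus cKO 3, those of Gpld1 and Fdxacb1 (adjusted p = 0.193 for each), Pcdhb19 (0.0978) and Pcdhb22 (0.0538).

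Of the gene lists, 9 were called on the arrays labelled hippocampus, and the protocadherin beta list alone held with an estimated correlation (adjusted p = 0.0285). Microglial genes had a median of 0.41 (adjusted p = 3.61e-06, and adjusted p = 0.825 with an estimated correlation), and without the matching arrays the median was 0.20 and the list was not called (adjusted p = 0.289). Fcgr3 was its 1 call over all probe sets (1.52, SE 0.24, and 0.98 without the matching arrays). Its adjusted p was 0.132 without hippocampus cKO 3. Hippocampal subfield genes had a median of -0.27 (adjusted p = 0.000106, and adjusted p = 0.787 with an estimated correlation), with 19 of 21 changes negative, and -0.18 with 15 of 21 negative (adjusted p = 0.00153) without the matching arrays. As labelled, 2 of 3 cKO arrays but 1 of 3 control arrays have cortical levels, which by itself lowers hippocampal genes in this comparison. Deep layer genes had a median of -0.18 (adjusted p = 0.000106, and adjusted p = 0.172 with an estimated correlation), with 2 falls over all probe sets and 7 adjusted over the list alone, among them Fezf2 and Nxph3 (-0.68, SE 0.12, and -0.70 without the matching arrays). Once the matching arrays were left out, the deep layer median was -0.01, with 9 positive and 10 negative changes and a mean of -0.24 (adjusted p = 0.00153), and limma called 0 members over all probe sets and 4 adjusted over the list alone. Cholesterol synthesis genes had a median of -0.20 (adjusted p = 0.000106, and adjusted p = 0.787 with an estimated correlation), and heat shock genes one of 0.21 (adjusted p = 0.00529, and adjusted p = 0.165 with an estimated correlation). Neither was called without the matching arrays, at -0.10 (adjusted p = 0.209) and 0.15 (adjusted p = 0.0682). Activity-regulated genes had a median of -0.09, oligodendrocyte genes one of 0.21 and cohesin genes one of 0.14, none of them called with an estimated correlation (adjusted p = 0.699, 0.866 and 0.866). Their medians without the matching arrays were -0.14 (adjusted p = 0.00192), 0.06 (adjusted p = 0.861, not called) and 0.23 (adjusted p = 0.00266). Without the 3 matching arrays 11 lists were called and none with an estimated correlation, where the protocadherin beta list had an adjusted p of 0.243, and without hippocampus cKO 2 alone 16 were called. Of the 11, 6 were not called as labelled. These were neuropeptide genes (median -0.22, adjusted p = 0.000158), neuronal maturation genes (-0.15, 0.00192), interferon response genes (0.22, 0.00416), Hox genes (-0.14, 0.00462), potassium channel genes (-0.04, 0.0113) and nonclustered protocadherins (0.12, 0.0370), with adjusted p of at least 0.797 with an estimated correlation.

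The genes called in cortex were followed into the 3 arrays labelled hippocampus that match no cortex array. Of the 125 probe sets higher in cKO over the cortex arrays alone, 114 had a positive change there, with a median of 0.44. Of the 271 lower ones, 237 had a negative change, with a median of -0.34. These medians lay beyond those of all 10000 random lists of the same size. Random lists treat probe sets as if they varied separately, and the changes rest on 1 cKO array against 2 control arrays. The rank therefore does not measure the spread between animals. Across these 396 probe sets, which are not independent replicates, the changes in the 2 regions had a Pearson r of 0.778 and a slope through 0 of 0.50, and over all probe sets r was 0.170. Y-linked signal was missing on 2 of 4 cKO and 0 of 4 control arrays in cortex, and here on the only cKO array and 1 of 2 control arrays. As it was unbalanced in the same direction in both comparisons, this likeness is not free of it. As labelled, 27 of the 33 higher and 44 of the 45 lower hippocampus calls were also cortex calls, against 0.151 and 0.478 for independent lists (one-sided Fisher's exact p = 2.20e-59 and 1.18e-87). These overlaps share the 3 matching arrays with cortex, and without them, or with each region fitted alone, the overlap was 0, since limma called at most 1 probe set in hippocampus.

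**Figure D5:**
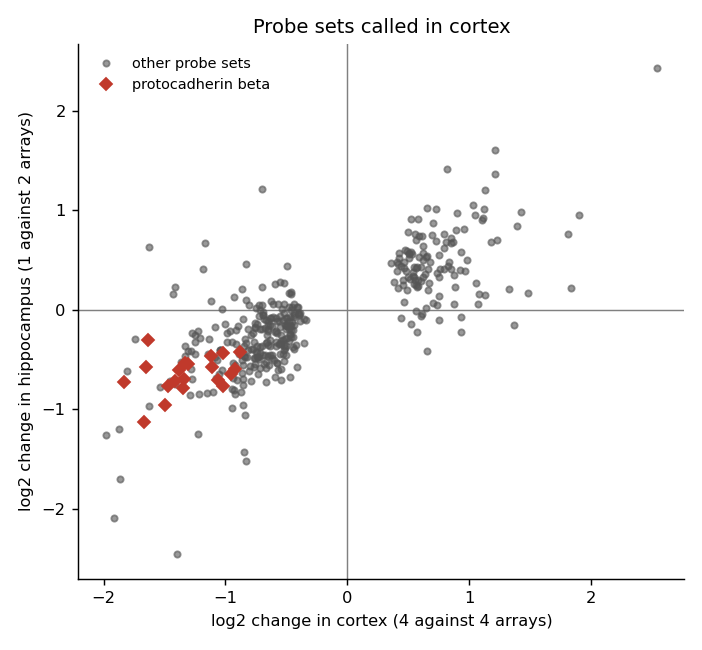
Log2 change, cKO minus control, of the 396 probe sets called over the cortex arrays alone, in cortex (x axis, 4 arrays against 4) and on the 3 arrays labelled hippocampus that match no cortex array (y axis, 1 against 2). Red diamonds are protocadherin beta isoforms. Most points share their sign, 114 of the 125 higher and 237 of the 271 lower ones.

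Averaged over the labelled regions, 677 probe sets passed, 314 higher and 363 lower, with Ctcf at -1.28 (SE 0.09, adjusted p = 1.41e-05). Without the matching arrays, 271 passed, which became 93 when Y-linked signal was added as a covariate. The count of genes changed on average over both regions fell to 446 without hippocampus cKO 1 and 432 without hippocampus cKO 3, and rose to 1085 without hippocampus cKO 2. A test of the difference between the regions called 0 probe sets by limma, with 300 at an unadjusted p under 0.05. Without the 3 matching arrays it called 2, as it did without hippocampus control 2 alone. Of the first 2, Rprm changed by -1.74 in cortex and -0.29 in hippocampus (difference 1.45, SE 0.13, adjusted p = 0.0228), and the unnamed probe set 4332799 changed by 0.29 and -2.32 (difference -2.61, SE 0.24, adjusted p = 0.0228).

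For gene lists, 5 differed between the labelled regions and none did with an estimated correlation (adjusted p = 0.949 for each). The protocadherin beta isoforms were less reduced on the arrays labelled hippocampus, by a median of 0.28 with all 22 differences positive (adjusted p = 3.22e-06). Without the matching arrays the median was 0.57. Ctcf itself also fell less there, by -0.75 against -1.42 in cortex. The 396 probe sets called over the cortex arrays alone had a slope of 0.50 there. A smaller change in hippocampus was thus not particular to this list. Potassium channel genes differed by a median of 0.21 (adjusted p = 0.000156) and hippocampal subfield genes by -0.17 (adjusted p = 2.94e-05). Hox genes differed by -0.07 (adjusted p = 0.0284) and choroid plexus genes by -0.13 (adjusted p = 0.0479), an order that turned round for choroid plexus without hippocampus control 3 (adjusted p = 0.725). With the matching arrays left out, the median was 0.11 for potassium channels (adjusted p = 0.484, not called), -0.14 for hippocampal subfields (adjusted p = 0.00960), -0.09 for Hox genes (adjusted p = 0.0103) and 0.04 for choroid plexus (adjusted p = 0.919, not called). There 6 lists were called, none with an estimated correlation (adjusted p = 0.959 for each). The 3 that were not called as labelled were neuronal maturation genes (median -0.10, adjusted p = 0.00960), deep layer genes (0.16, 0.0160) and neuropeptide genes (-0.22, 0.0219). The count of 5 lists was 10 without cortex control 4, 12 without hippocampus control 2 and 13 without hippocampus cKO 2.

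Between hippocampus and cortex in control mice, the hippocampal genes Prox1, Lhx9, Zbtb20 and Fibcd1, the last a gene of CA1 neurons, and the upper layer genes Rorb, Cux2 and Cux1 differed once the matching arrays were set aside. As labelled, none of these 7 passed limma's test (Prox1 1.40, adjusted p = 0.206, Rorb -1.55, adjusted p = 0.118). Prox1, Zbtb20, Fibcd1, Rorb and Cux2 were also chosen, after their values were seen, to show the cortical levels of the matching arrays. Their differences without these arrays are therefore no separate support for leaving them out. Without the matching arrays the log2 difference was 2.22 for Prox1 (adjusted p = 0.000110), 2.66 for Lhx9 (adjusted p = 1.65e-05), 2.27 for Zbtb20 (adjusted p = 2.81e-05) and 1.80 for Fibcd1 (adjusted p = 8.95e-06). It was -2.21 for Rorb (adjusted p = 6.51e-05), -1.82 for Cux2 (adjusted p = 2.74e-05), and Cux1 was 2.82-fold lower (adjusted p = 2.74e-05). The differences within the 3 matching pairs also followed the level of a probe set (Spearman correlation -0.414 across probe sets), and 3396 probe sets had a mean pair difference above 1.2-fold, so the labels also differ by a shift whose source is open. With that mean pair difference subtracted, where SE and p leave out the error of a shift taken from 3 pairs, Prox1 stood at 2.46 (SE 0.16, adjusted p = 6.41e-05), Lhx9 at 2.23 (SE 0.13), Zbtb20 at 2.19 (SE 0.13), Fibcd1 at 1.48 (SE 0.07), Rorb at -2.07 (SE 0.15), Cux2 at -1.69 (SE 0.10) and Cux1 at -1.31 (SE 0.09).

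As labelled, 635 probe sets differed between hippocampus and cortex controls, 505 higher and 130 lower in hippocampus. Without the matching arrays 2913 did, 1446 higher and 1467 lower, and 1124 with the mean pair difference subtracted, 338 higher and 786 lower. The 5 genes highest in hippocampus as labelled were Ifi203 (2.40, SE 0.46), Olfr732 (2.15, SE 0.49), Olfr1260 (1.58, SE 0.22), E330013P04Rik (1.57, SE 0.36) and Olfr116 (1.51, SE 0.31). The cortex control levels of Ifi203, Olfr732 and Olfr116, 1.89, 1.81 and 2.86, lay below the olfactory receptor median, and with the pair difference subtracted Ifi203 (1.58) and E330013P04Rik (1.20) still passed while Olfr1260 stood at 0.54 (adjusted p = 0.173). The 5 lowest were Pou3f2, an upper layer transcription factor (-1.58, SE 0.33), Nat8f1 (-1.04, SE 0.21), Rasgrp2 (-0.98, SE 0.23), Ccn2, a gene of subplate neurons (-0.96, SE 0.20), and Kcnh1 (-0.95, SE 0.23). With the pair difference subtracted Pou3f2 stood at -1.48, Rasgrp2 at -1.09, Ccn2 at -1.05 and Kcnh1 at -1.21, all 4 passing, and Nat8f1 at -0.06 (adjusted p = 0.927). Of these 10 genes Olfr1260 alone kept its call without every single array, and without hippocampus control 1 the adjusted p of the others reached up to 0.244 (Kcnh1). The count of 635 genes different between hippocampus and cortex in controls fell to 236, 277 and 305 without cortex control 1, 2 and 4, to 409 and 381 without cortex cKO 1 and 2, and to 71 and 97 without hippocampus control 1 and 3, and was 2627 without hippocampus control 2. The 2913 became 1772 when Y-linked signal was added as a covariate.

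Of the lists, 10 were called between the labelled regions and none with an estimated correlation (adjusted p of at least 0.670). Hippocampal subfield genes were higher by a median of 0.54 (adjusted p = 0.00168), with 1 rise over all probe sets and 7 adjusted over the list alone, and upper layer genes lower by 0.34 (median -0.34, adjusted p = 0.00418), with 1 fall over all probe sets and 2 rises and 10 falls adjusted over the list alone. Choroid plexus genes were higher by a median of 0.50 (adjusted p = 0.000628), among them F5 (0.73) and Ecrg4 (0.76), which lost their calls without hippocampus control 1 (adjusted p = 0.154 and 0.182). With the pair difference subtracted, 13 lists were called, none with an estimated correlation. There the hippocampal subfield median was 0.47, with 8 genes higher and 1 lower, the upper layer median was -0.56, with 1 higher and 11 lower, and the choroid plexus median was 0.53, with 6 higher. F5 then stood at 0.38 (adjusted p = 0.121), Otx2 at 0.70 (adjusted p = 0.0459) and Sostdc1 at 0.83 (adjusted p = 0.0369). Also called as labelled were cohesin genes (median -0.27), Hox genes (0.27), potassium channel genes (-0.21), reactive astrocyte genes (0.31), deep layer genes (-0.24), astrocyte genes (0.27) and synapse adhesion genes (-0.13). All 10 were called without the matching arrays, with medians of 0.72 for hippocampal subfields, -0.53 for upper layers, 0.65 for choroid plexus, -0.36 for cohesin, 0.33 for Hox, -0.20 for potassium channel, 0.36 for reactive astrocyte, -0.39 for deep layer, 0.46 for astrocyte and -0.16 for synapse genes. Cadherins (-0.30, adjusted p = 0.00248) and progenitor genes (0.30, adjusted p = 0.00144) were called there as well, and none of these 12 with an estimated correlation (adjusted p of at least 0.208).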

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

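The tests of the same sample, of normalization, of Neurod6, of the share of hippocampal RNA, of probe sets chosen in arrays without Y-linked signal, and of splits without the matching arrays were chosen only after the result was seen. The 3 arrays labelled hippocampus that match a cortex array differed from it by an SD at most 0.586 times the lowest of any other pair. That restates how the pairs were found, and by itself leaves open whether they come from the same sample. Across probe sets the differences within the 3 pairs correlated at 0.687 to 0.688. With their mean subtracted, a pair difference had an SD of at most 0.097, though that mean came from the same 3 pairs. Whether a pair shares a sample was not tested further. A mixture of cortical tissue into the dissection was tested by the position of each matching array between its cortex array and the other hippocampus arrays, where the highest median was 0.284. That test was not specific, because the differences within the pairs followed the level of a probe set (Spearman correlation -0.414), which a different normalization of the arrays labelled hippocampus could produce. Over 14 probe sets at least 4-fold higher in hippocampus, the implied share of hippocampal RNA was at most 2.58%, so most of the RNA on these arrays was unlikely to be hippocampal, while a share under 10% stays open.

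For the 355 calls in cortex the real split alone (1 of 35) gave as many, and the highest of the other splits gave 0. No smaller share is possible with 35 splits. Every other split mixes cKO and control arrays, so a real change widens the spread within its groups and lowers its calls. No other grouping gave as many calls, but chance was not excluded by this. With the cortex arrays alone the real split gave 396 calls and the highest other 1, with the same limits. Whether the 2 cortex cKO arrays without Y-linked signal carried some of the calls stays open. The median ratio of the change in the other 2 cKO arrays to that in these was 0.994, and the calls kept a median ratio of 0.997 without these 2 arrays, but both over probe sets called across all 4. Over 355 probe sets chosen in these 2 arrays and 2 controls, the ratio in the other 4 cortex arrays ranged from 0.381 to 0.729 over the 6 choices of controls. The sign was shared by 71.8% to 82.0% of these probe sets. Choosing by the smallest p lowers such a ratio by itself, and no like choice was made with the other 2 cKO arrays. Probe sets at or below background made up 0.563% of the calls.

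On the arrays labelled hippocampus there were too few splits to exclude chance, with 78 calls in the real split and 1490 in the highest other, among 2 of 10 with as many. That other split set the 3 matching arrays against the remaining 3, which points to a structure of the samples. For the average over the regions the real split gave 677 calls and the highest other of 100 gave 590 (1 with as many), from the same structure, in a fit that counts the matching arrays as separate samples. Without them no other of 100 splits gave as many calls as the real one. Hippocampus then has 1 cKO array, so chance was not excluded there either. For the difference between regions, with 0 calls in the real split, all 100 splits give as many by definition, so they say nothing about chance, and the highest other gave 714. Between control regions the real split gave 635 calls and the highest other of 35 gave 204 (1 with as many), which grouped hippocampus control 2 with cortex control 2 and 3. That fit counts hippocampus control 2 and the cortex array it matches as separate samples and was not repeated without one of them, so chance stays open there.

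In cortex the upper end of the 95% interval of the Neurod6 change was -1.25. Loss of 1 of 2 gene copies to the Cre insertion would give a smaller fall, if signal follows copy number. That reading also assumes 1 Cre allele in each cKO mouse, which was not checked. On the unmatched arrays labelled hippocampus Neurod6 stood at -1.19 (SE 0.36), where its fall was not set against loss of 1 copy.

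Dixon's test, which by chance marks about 1 in 20 groups, marked 7 of 230 groups of 4 arrays, with 11.5 expected. In cortex controls these were Neurod6 (0.933, array 4 at 10.05, next 10.30), Trem2 (0.865, array 4 at 6.78, next 6.41), Gjb6 (0.906, array 4 at 7.65, next 7.29), Kcnj6 (0.844, array 1 at 7.08, next 6.84) and Npy (0.859, array 2 at 8.91, next 9.20). In cortex cKO they were Fdxacb1 (0.855, array 3 at 6.62, next 6.91) and Mdp1 (0.871, array 1 at 7.09, next 6.75).

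The change in cKO differed between the labelled regions for 5 gene lists, none of them called with an estimated correlation (adjusted p = 0.949 for each). Otherwise the adjusted p was 3.22e-06 for the protocadherin beta cluster, 2.94e-05 for hippocampal subfields, 0.000156 for potassium channels, 0.0284 for Hox genes and 0.0479 for choroid plexus. Without the matching arrays potassium channels (0.484) and choroid plexus (0.919) were not called. In that fit the change differed for Rprm by 1.45 and for the unnamed probe set 4332799 by -2.61.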

How the results depend on the processing

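The number of arrays in hippocampus, and its fall to 3 without the matching arrays, limits these results. The cause of each moved value was not tested. Counts of genes changed or different in this section are counts of called probe sets. The 355 genes changed in cortex became 679 with array weights, 226 at a fold of 1.5, 56 without the arrays that lack Y-linked signal, and 207 to 428 without 1 array.

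The 78 genes changed in hippocampus became 172 with quantile normalization again, 142 with centred arrays, 120 with trend and robust, 351 with array weights, 157 with 1 probe set per gene, 0 with the compared groups only, 1 without the matching arrays, 0 with Y-linked signal as a covariate as well, and 14 to 274 without 1 array.

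The 677 genes changed on average over both regions became 1467 with array weights, 272 at a fold of 1.5, 271 without the matching arrays, 93 with the Y-linked covariate as well, and 432 to 1085 without 1 array. The genes whose change differs between regions numbered 0, and 2 without the matching arrays, 2 with the Y-linked covariate as well, and 0 to 2 without 1 array.

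The 635 genes different between hippocampus and cortex in controls became 100 with quantile normalization again, 329 with centred arrays, 290 with trend and robust, 1957 with array weights, 1123 with 1 probe set per gene, 312 at a fold of 1.5, 1 with the compared groups only, 2913 without the matching arrays, 1772 with the Y-linked covariate as well, 1124 without them and with the mean pair difference subtracted, and 71 to 2627 without 1 array.

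Protocadherin beta falls in cortex went from 20 to 6 without the arrays that lack Y-linked signal. In hippocampus 10 became 18 with quantile normalization again, 18 with centred arrays, 4 with contrasts without moderation, 20 with array weights, 17 with 1 probe set per gene, 0 without the matching arrays, 0 with the Y-linked covariate as well, 21 adjusted over the list alone, and 1 to 18 without 1 array. The Ctcf p in hippocampus was 0.1 by the exact permutation test. The overlap of calls, 27 higher and 44 lower, became 0 and 0 with each region fitted alone, and 0 and 0 without the matching arrays.

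In cortex, control and cKO arrays of the same replicate number correlated between -0.06 and 0.05, which gives no sign of pairing. In hippocampus the correlations of the same number were between -0.38 and 0.10. The 3 arrays that match a cortex array enter these values, so they cannot decide on pairing there. With replicate number as a block there were 142 genes changed in cortex, 10 genes changed in hippocampus and 356 genes changed on average over both regions. There were then 40 genes different between hippocampus and cortex in controls and 0 for protocadherin beta in hippocampus. With a random block of genotype and number across regions there were 1176 for the average and 172 between regions. The consensus correlation of that block was -0.288. A negative value narrows the error of an average over regions and widens that of a difference, so 1176 is no sign of more change. The matching arrays also carry other numbers than the cortex arrays they match.

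Of 9 lists called in cortex 2 were called with an estimated correlation and 2 with fry. In hippocampus 1 of 9 was called with an estimated correlation and 3 with fry, which called 4 lists in all, and the count was 8 to 16 without 1 array. For the difference 5 became 0 and 0, and 4 to 13 without 1 array. Between regions as labelled none of the 10 was called with an estimated correlation (0) or with fry, whose 1 call was another list, blood. With the matching arrays left out, fry called more lists between regions. The adjusted p of the choroid plexus list for the difference ranged from 0.000103 to 0.725 without 1 array, and its direction turned without hippocampus control 3 (0.725) and with the Y-linked covariate without the matching arrays (0.988). Pcdhb1 in cortex ranged from -0.12 (without cortex control 1) to 0.40 without 1 array.

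For 94 named genes in cortex 1969 of 2161 values kept their call, 170 were weaker and 21 stronger. In hippocampus 633 of 896 values of 39 genes kept it, and between regions 335 of 525 values of 22 genes.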

Other observations

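The tests of neighbouring genes and of position in the protocadherin cluster were chosen only after the result was seen. Interneuron genes were not called in cKO cortex. Npy, a neuropeptide of interneurons, stood at -0.25 (SE 0.10, n = 4 per group, adjusted p = 0.366) and Pvalb at 0.25 (SE 0.13, adjusted p = 0.560). Among other genes of excitatory neurons, Neurod2, a relative of Neurod6, stood at -0.35 (SE 0.12, adjusted p = 0.261), and the type II cadherin Cdh8 at 0.27 (SE 0.11, adjusted p = 0.415).

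Genes called in cortex lay next to each other more often than in shuffled orders. Outside the protocadherin beta cluster 9 pairs of adjacent genes were called the same way, against a median of 3 and a highest of 12 in 10000 shuffles (permutation p = 0.0082), and 3 pairs were called in opposite ways. Examples, chosen after their values were seen, were Prkd1 and G2e3 (1.21 and 0.81), G2e3 and Coch (0.81 and 1.03), and Gpld1 and Dcdc2a (1.11 and 1.08). The call of G2e3 ended without single arrays (adjusted p of up to 0.0875). The shuffles treat genes as if they varied separately. Over the cortex arrays, with group means removed, the genes of a pair correlated at up to 0.854 (Prkd1 and G2e3). The lowest such correlation was -0.188 (Gpld1 and Dcdc2a). The permutation p therefore does not measure the spread between animals.

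The fall of the protocadherin beta isoforms grew along the cluster, with a Spearman correlation of isoform number and change of -0.673 over 21 isoforms (permutation p = 0.0012) and -0.715 with Pcdhb1. The control level had a correlation of -0.24 (permutation p = 0.294). These permutations treat the isoforms as independent, though all changes come from the same cortex arrays. The estimated inter-gene correlation of the list was 0.380 in the fit of all arrays. The permutation p therefore does not measure the spread between animals.

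Of the measured deep layer genes 78.9% had a negative change in cortex. Loss of deep layer neurons as a whole could give that share, as could lower expression within these neurons. The share was not specific to them and cannot decide this. Negative changes were found in 28 of 32 activity-regulated and all 18 cholesterol synthesis genes, and in 11 of 19 upper layer genes.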
